A study of Mus musculus with 8 samples.

How the data were processed

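Total RNA from whole liver, extracted with Trizol, was labelled with Cy3 from 0.1 ug per sample and hybridised to 8 arrays of 1 Agilent mouse expression slide with 1 scan time. The labels give sex, genotype, age (10 to 11 weeks) and a replicate number, and only replicates 3 and 4 of each group were used here. The spot signals are fluorescence intensities, background-subtracted and adjusted by Agilent Feature Extraction (version 11.5.1.1 per the file headers, 9.1.3.1 in the authors' notes). The deposited value table holds log2 values that the authors shifted by the 75th percentile of each array. It was checked against the spot signals and equalled their log2 minus the array's 75th percentile with control probes included (r = 1.0 on each array), without centring by gene. Wild-type samples lay in the outer columns of the slide and samples labelled Bcl6-deficient in the inner columns, for both sexes, and the replicate number was the slide row.

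Each array held 59305 spots for 56605 probes, 300 of them printed 10 times. No spot was saturated, 62 to 111 spots per array were marked as outliers and left out, and repeated spots varied by 3.24% to 5.55% (coefficient of variation). Signals were averaged per probe, taken to log2 and reduced by the array's 75th percentile (7.0713 to 7.6295). Probes were named by their RefSeq accession in a mouse gene table. This named 32994 probes of 22911 genes, 7899 of them with more than 1 probe, and left 23611 probes under the name the array gives. The array was designed on mm9 and the gene table is of a later build, so no positions are given. A probe was kept if well above background on both arrays of at least 1 group, and the brightest probe stood for its gene, which left 23866 genes, 14488 of them with a symbol. The others stand under the name the array gives and are counted as genes here. Some of them may repeat a named gene, as XIST does.

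The 4 group means were fitted with limma 3.58.1 in R 4.3.3, with a moderated t-test whose variance follows intensity (4 residual and 4.8 prior degrees of freedom). The contrasts tested were sex in wild-type livers, genotype label in males, genotype label in females, sex in livers labelled Bcl6-deficient, and the interaction. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Gene lists written from general knowledge (36 lists, 863 of 887 members on the array) covered sex-biased genes, metabolism, immune responses and cell types. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and also with a correlation estimated from the data and with limma's fry. With 4 residual degrees of freedom the estimated correlation is itself imprecise.

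The samples, contrasts, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names, per contrast, the 10 largest changes in each direction among genes past the threshold that have a symbol, whose groups do not overlap and that are above background on every array compared. To these come up to 5 genes per direction with the largest lower bound of the fold, genes named in advance, and list members with the largest changes or lowest p-values. Some genes that the rule names are not reported here, and counts and lists include them. Alternatives changed the background correction, normalization, filter, outlier marks, source of values, variance model, arrays in the fit, probe choice and set test, added the replicate number as a block, or left out each array in turn. The normexp alternative used median spot signals, since mean signals were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

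The method was tested on simulated data with 200 of 23866 genes changed in males labelled Bcl6-deficient, in 20 simulations. It recovered 14.2% of changes of 0.58, 58.7% of changes of 1, 92.0% of changes of 2 and 99.0% of changes of 3 (log2), with 11.1 false calls on average and 20 at most. A list of 25 genes raised together was called in 20 of 20 simulations, and 3 of 1420 tests of lists without a planted change made a call. The simulated noise was independent between genes, while the estimated correlation within the real lists reached 0.788 (major urinary proteins). The false list calls of the simulations therefore do not give their rate in these data. Each simulation also changed far fewer genes than the 3269 called in males.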

Results

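Gene expression was measured in whole liver of male and female C57BL6 mice aged 10 to 11 weeks on 1-colour Agilent microarrays. The 8 samples formed 4 groups of 2: male wild-type, male labelled liver-specific Bcl6-deficient, female wild-type and female labelled liver-specific Bcl6-deficient. Each array measured 56605 probes, of which 28073 to 30624 (49.59% to 54.1%) were well above background. Arrays of the same group correlated at r = 0.9902 to 0.9936 across genes. The number of arrays limits the precision of every value below. The labels say only that the replicates are separate samples, so the p-values measure only the spread between these samples. Levels are log2 signals relative to the 75th percentile of the array. Differences are log2 values with their standard error from limma, n = 2 arrays per group. Adjusted p-values are over the 23866 genes tested unless stated otherwise. Levels between -4.38 and -3.85 were the lowest that counted as above background, depending on the array. Where a gene was not well above background on any array of a group, "at least N-fold" compares the mean of the brighter group with the lowest signal counted as above background, or the dim probe's own signal if that was higher.

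The targeted gene and the sex of the samples came first. The Bcl6 signal was not lower in arrays labelled Bcl6-deficient. It was 3.19 and 3.55 in male wild-type livers, 4.30 and 4.85 in male livers labelled Bcl6-deficient, 2.02 and 4.16 in female wild-type livers and 4.04 and 4.81 in female livers labelled Bcl6-deficient. The difference labelled Bcl6-deficient minus wild-type was 1.21 ± 0.57 in males (adjusted p = 0.203) and 1.34 ± 0.57 in females (adjusted p = 0.232). Leaving out female wild-type replicate 4 gave 2.41 in females (adjusted p = 0.00359) and an adjusted p of 0.0202 in males, and leaving out female wild-type replicate 3 gave the same 0.0202 in males. The array has 1 Bcl6 probe. The part of Bcl6 that was deleted and the position of the probe in it are not known here, and a probe outside the deleted part checks nothing. The direction of every genotype difference below therefore rests on the labels.

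Xist, the RNA that silences an X chromosome, was 0.76 ± 0.19 (SD, n = 2) in female wild-type livers and 0.55 ± 0.20 in female livers labelled Bcl6-deficient, and not well above background on any male array. By their brightest probes, the Y-linked transcripts Ddx3y, Uty and Kdm5d were well above background on all 4 male arrays and on no female array. Their male levels were -0.97 ± 0.19, -0.91 ± 0.10 and -0.41 ± 0.24 in wild-type livers. Another Kdm5d probe was not above background on any array. Eif2s3y was at 2.29 ± 0.05 in male wild-type livers, and 1 of its probes was above background on 1 female array labelled Bcl6-deficient while its other probe was not.

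**Figure D1:**
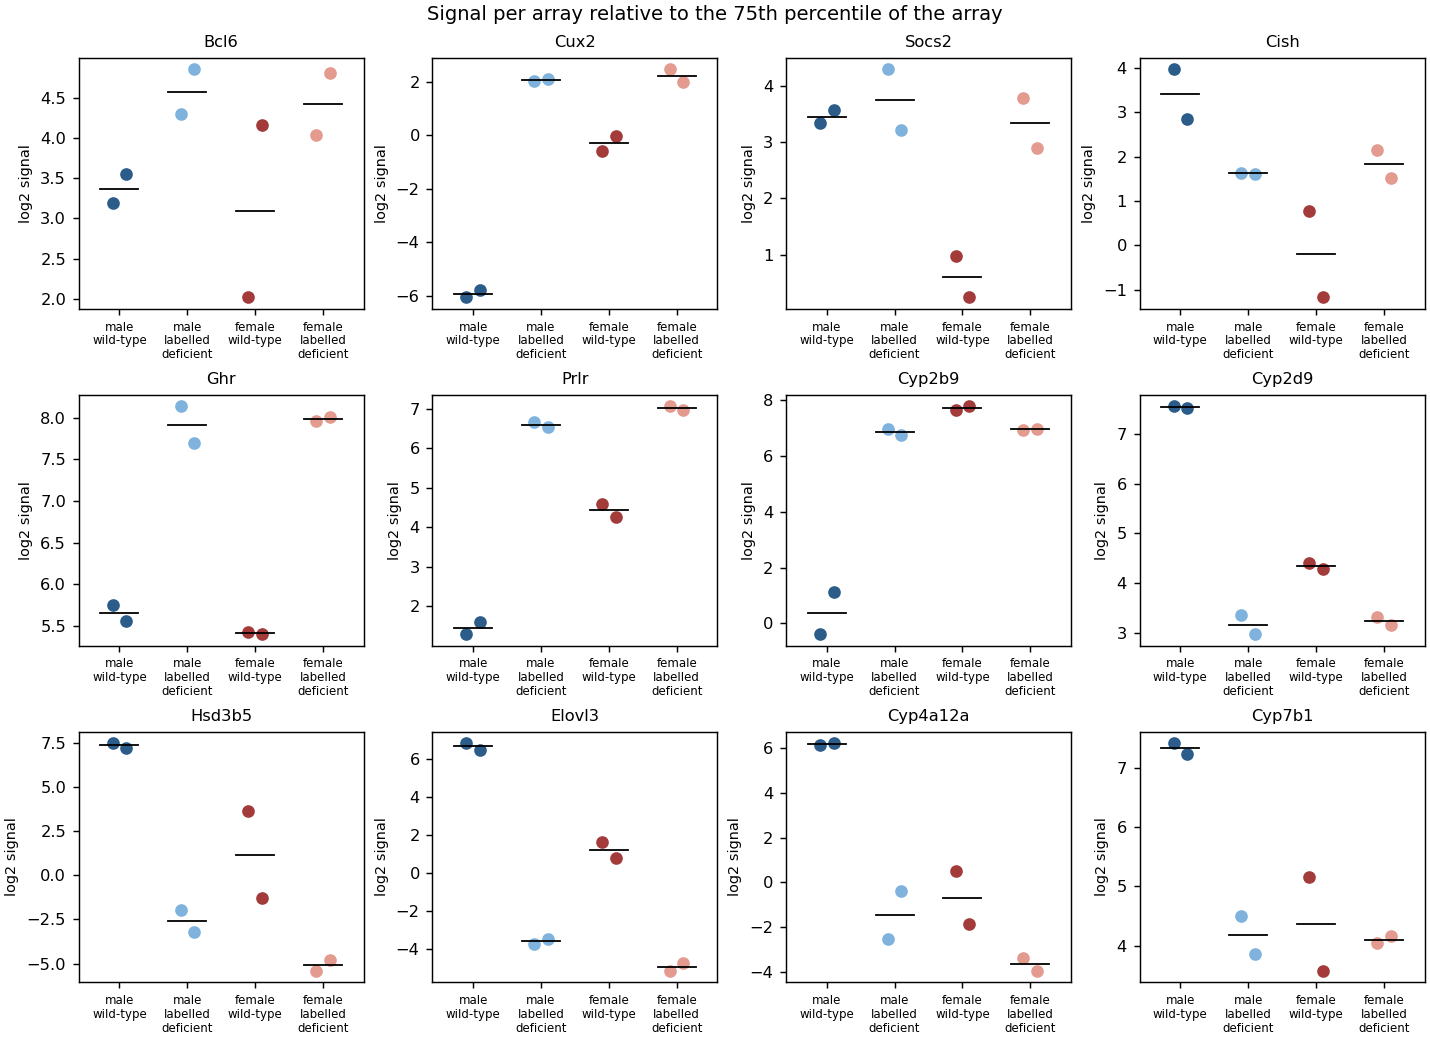
Signal of 12 genes on each of the 8 arrays (log2, relative to the 75th percentile of the array); each point is an array and each line a group mean, and levels below about -4 are at or under background. Cux2 is at background in male wild-type livers and above it in the other 3 groups, and Bcl6 ranges from 2.02 to 4.85 without a lower level in arrays labelled Bcl6-deficient.

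The first comparison asked which genes differed between the sexes in wild-type liver. Male livers had far more of the cytochrome P450 enzymes Cyp4a12a (6.87 ± 0.78, male minus female, adjusted p = 0.00218) and Cyp2d9 (3.21 ± 0.14, adjusted p = 5.58e-06), of the fatty acid elongase Elovl3 (5.44 ± 0.28, adjusted p = 1.83e-05) and of the acetyltransferases Nat8f5 (6.34 ± 0.40) and Nat8 (4.59 ± 0.31). Female livers had more of the cytochrome P450 enzymes Cyp2b9 (-7.34 ± 0.38, adjusted p = 2.08e-05) and Cyp2b10 (-5.93 ± 0.36), of the acyl-CoA thioesterase Acot3 (-4.89 ± 0.43) and of the lipoprotein receptor Vldlr (-3.86 ± 0.41). Cyp2b13 was at least 1326-fold higher in females (adjusted p = 3.53e-07), A1bg at least 378-fold, and the sulfotransferases Sult2a2 and Sult2a6 at least 313-fold and 278-fold. The last 3 bounds rest on female arrays that differed: without female wild-type replicate 3 they were 152-fold for A1bg, 1360-fold for Sult2a2 and 1275-fold for Sult2a6, and without replicate 4 they were 938-fold, 71.9-fold and 60.4-fold. Cyp3a41a did not differ past the threshold (-0.20 ± 0.12, adjusted p = 0.406). Nearly identical gene copies may share probe signal in the Cyp2b, Cyp3a41, Cyp4a12, Sult2a and major urinary protein families, which was not tested, so the share of each copy is uncertain.

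In all, 804 genes passed the threshold in wild-type liver, 365 higher in males and 439 higher in females, 490 of them at least 2-fold. Of the 804, 602 had a symbol. Further genes higher in males were Cyp4a12b (6.99), Hsd3b5 (6.20), Serpina4-ps1 (6.17), Cyp2d34 (4.09), the asparagine synthetase Asns (3.92) and Cib3 (3.90). Moxd1, Lama3 and Capn8 were at least 14.6-fold, 13.2-fold and 12-fold higher in males, and Eif2s3y and Kdm5d at least 95.4-fold and 14.7-fold. The Moxd1 bound was 4.69-fold without male wild-type replicate 3 and 45.6-fold without replicate 4. Hsd3b5 was at 3.64 and -1.29 on the female wild-type arrays. Further genes higher in females were Hamp2 (-3.68), the metallothionein Mt1 (-3.49), Cyp17a1 (-3.33), the ectonucleotidase Nt5e (-3.10), Acnat2 (-2.99) and the prolactin receptor Prlr (-2.98). The count fell to 364 without male wild-type replicate 3, 436 without male wild-type replicate 4 and 456 without female wild-type replicate 4. Without male wild-type replicate 3 the calls of Cyp4a12b (adjusted p = 0.051), Hsd3b5 (0.145), Asns (0.0563), Moxd1 (0.0613) and Hamp2 (0.103) ended. Those of Moxd1 (0.0754) and Hamp2 (0.091) also ended without female wild-type replicate 4, and that of Hsd3b5 also without male wild-type replicate 4 (0.124) or either female array labelled Bcl6-deficient (0.0524).

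Gene lists fixed in advance gave the same picture by group. Of 32 genes long known as male-biased in mouse liver, 21 were higher in males and 0 lower over all genes tested, and 30 and 0 adjusted over the list alone (median 1.77, limma's camera test, adjusted p = 4.58e-24, and adjusted p = 0.333 with an estimated correlation). Of 50 known female-biased genes, 38 were higher in females and 0 in males, and 45 and 0 adjusted over the list alone (median -2.82, or -2.53 with bounds, adjusted p = 1.53e-49, and adjusted p = 0.0519 with an estimated correlation). Of 40 interferon response genes, which serve antiviral defence, 16 were higher in females and 0 in males, and 26 and 0 adjusted over the list alone (median -0.66, adjusted p = 3.81e-19, and adjusted p = 0.0781 with an estimated correlation). They included Gbp3 (-1.98 ± 0.17), Gbp6 (-1.38 ± 0.15) and Ifit1 (-1.31 ± 0.16). Lists of markers of other cell types also tested higher in females by camera, but most of their members did not pass and the calls were lost with an estimated correlation. Of 24 Kupffer cell and macrophage genes, 0 were higher in males and 2 in females, and 0 and 6 adjusted over the list alone (median -0.53, adjusted p = 3.82e-05, and adjusted p = 0.552 with an estimated correlation). Of 20 endothelial genes, 0 passed in either direction, also over the list alone (median -0.22, adjusted p = 0.000114, and adjusted p = 0.552 with an estimated correlation). Of 16 T and natural killer cell genes, 1 passed, higher in males, also over the list alone (median -0.66, adjusted p = 0.00818, and adjusted p = 0.568 with an estimated correlation). Of 19 stellate cell and 8 B and plasma cell genes, 0 passed in either direction, also over the list alone (medians -0.15 and -0.38, or -0.15 with bounds for the latter, adjusted p = 0.0195 and 0.0408, and adjusted p = 0.568 with an estimated correlation for both). Without female wild-type replicate 4 the calls of the T and natural killer cell (adjusted p = 0.552), stellate (0.13) and B and plasma cell (0.952) lists ended. That of the stellate list also ended without male wild-type replicate 4 (0.0798), and those of the T and natural killer cell (0.163) and B and plasma cell (0.145) lists without male wild-type replicate 3. Of 35 genes of growth hormone signalling, 7 were higher in males and 6 in females, and 8 and 7 adjusted over the list alone (median 0.07, mean -0.09, adjusted p = 0.711 by camera). Socs2 and Cish, feedback inhibitors of the growth hormone receptor, were higher in males (2.86 ± 0.39 and 3.62 ± 0.57), and Cux2, a female-specific transcription factor, was at least 12.6-fold higher in females. The Cish call ended without male wild-type replicate 3 (adjusted p = 0.087) and the Socs2 call without male wild-type replicate 4 (adjusted p = 0.0507). Igf1, Ghr and Stat5b did not differ past the threshold between the sexes (-0.09, 0.24 and -0.30).

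The second comparison asked what differed in male livers labelled Bcl6-deficient. Most female-biased genes of the fixed list rose and most male-biased ones fell, though camera's calls of both lists were lost with an estimated correlation (adjusted p = 0.104 and 0.425). Cyp2b9 rose by 6.49 ± 0.38 (adjusted p = 1.27e-05), Cyp2b10 by 5.45 ± 0.36, Acot3 by 6.55 ± 0.43 and Prlr by 5.15 ± 0.15. Sult2a1, Sult2a6, Sult2a2 and Sult2a4 became at least 5197-fold, 2720-fold, 1806-fold and 1527-fold higher, and A1bg at least 1916-fold. Elovl3 fell by 10.23 ± 0.28 (adjusted p = 1.93e-07), the steroid dehydrogenase Hsd3b5 fell by 9.94 ± 1.23, Cyp4a12b fell by 7.81, Cyp4a12a fell by 7.65 ± 0.78 and Cyp2d9 fell by 4.39 ± 0.14.

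In all, 3269 genes changed in males, 1717 higher and 1552 lower, 1615 of them at least 2-fold. Of the 3269, 2315 had a symbol. Other large increases were in the dynein chain Dnah11 (6.59), the secreted glutathione peroxidase Gpx3 (6.06), Hamp2 (5.79), the metallothioneins Mt2 (5.66) and Mt1 (4.41), Ankrd2 (5.47) and the protease Tmprss4 (5.40). Other large decreases were in Nat8 (-5.70), the transcription factor Pax2 (-5.25), the adrenergic receptor Adrb3 (-4.90), Clec2h (-4.42) and Olfr806 (-4.27). Ces4a, Olig1, Moxd1, Capn8 and Atp12a became at least 13.6-fold, 13.2-fold, 12.8-fold, 10.5-fold and 7.63-fold lower. Without male wild-type replicate 3 or 4, or male Bcl6-deficient replicate 3 or 4, the count was 2003, 1889, 2100 and 1740. Calls ended for Clec2h without male wild-type replicate 3 (adjusted p = 0.0639), male wild-type replicate 4 (0.0609) or male Bcl6-deficient replicate 3 (0.0639), and for Moxd1 without male Bcl6-deficient replicate 4 (0.0712). The Moxd1 bound was 4.12-fold without male wild-type replicate 3 and 40-fold without replicate 4.

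Of the 50 female-biased genes, 42 rose in males and 1 fell, and 44 and 1 adjusted over the list alone (median 2.74, with bounds also 2.74, camera adjusted p = 2.32e-34, and adjusted p = 0.104 with an estimated correlation). Of the 32 male-biased genes, 28 fell and 0 rose, and 29 and 0 adjusted over the list alone (median -2.64, or -2.13 with bounds, adjusted p = 1.38e-20, and adjusted p = 0.425 with an estimated correlation). Of the 35 growth hormone signalling genes, 7 rose and 4 fell, and 8 and 6 adjusted over the list alone. Cux2 rose at least 65.4-fold, Ghr, the growth hormone receptor, rose by 2.26 ± 0.15, the binding protein Igfbp1 rose by 2.70 ± 0.32 and the liver transcription factor Foxa1 fell by 2.77 ± 0.20. The differences in Socs2 (0.30), Cish (-1.79, adjusted p = 0.0716), Igf1 (0.10) and Stat5b (0.33) did not pass. Of the 40 interferon response genes, 16 rose and 0 fell, and 19 and 0 adjusted over the list alone (median 0.50, adjusted p = 5.32e-07, and adjusted p = 0.425 with an estimated correlation), among them Gbp6 (1.62), Gbp3 (1.60) and Zbp1 (1.51). Several lists of markers of other cell types had an upward camera test in males. Except in the erythroid list, most of their members did not pass over all genes. With an estimated correlation these calls were lost (adjusted p = 0.598 for T and natural killer cells and 0.515 for the others). Of 24 Kupffer cell and macrophage genes, 3 rose and 0 fell over all genes and over the list alone (median 0.37, adjusted p = 0.00115). Of 16 T and natural killer cell genes, 1 rose and 0 fell, and 6 and 1 adjusted over the list alone (median 0.91, adjusted p = 0.00115). Of 8 B and plasma cell genes, 3 rose and 0 fell, and 6 and 0 adjusted over the list alone (median 1.14, or 1.1 with bounds, adjusted p = 0.000967). Of 19 stellate cell genes, 3 rose and 0 fell, and 8 and 0 adjusted over the list alone (median 0.46, adjusted p = 0.000103). Of 20 endothelial genes, 3 rose and 0 fell, and 5 and 0 adjusted over the list alone (median 0.29, adjusted p = 0.000177). Of 9 erythroid genes, 4 rose and 1 fell, and 7 and 1 adjusted over the list alone (median 0.59, adjusted p = 0.0065). The call of the Kupffer cell list ended without male Bcl6-deficient replicate 4 (adjusted p = 0.105). The lists of 10 neutrophil genes (2 rose and 0 fell, also over the list alone, median 0.50, adjusted p = 0.0706) and 11 cholangiocyte genes (2 rose and 1 fell, also over the list alone, median -0.53, adjusted p = 0.455) did not pass.

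Lipid and bile acid genes moved both ways in males. Of 27 bile acid genes, 2 rose and 11 fell, and 3 and 15 adjusted over the list alone (median -0.39, adjusted p = 0.00463, and adjusted p = 0.515 with an estimated correlation). The oxysterol hydroxylases of bile acid synthesis Cyp7b1 (-3.15) and Cyp39a1 (-1.16) and the exporter Abcc3 (-1.98) fell, and the exporter Abcc4 rose by 1.65. Of 32 lipogenesis genes, 7 rose and 3 fell, and 7 and 5 adjusted over the list alone (median -0.13, mean 0.14, adjusted p = 0.789 by camera). The desaturases Fads1 and Fads2 rose by 2.17 and 2.03, and the lipase Pnpla3 became at least 10.1-fold higher. Of 52 genes of PPARA signalling and fatty acid oxidation, 11 rose and 5 fell, and 14 and 8 adjusted over the list alone (median -0.06, mean 0.31, adjusted p = 0.532 by camera), with increases in Acot4 (2.93) and the uncoupling proteins Ucp2 (2.46) and Ucp3 (2.41). Of 34 complement and coagulation genes, 6 rose and 7 fell, and 8 and 7 adjusted over the list alone (adjusted p = 0.825 by camera). The terminal complement components C6 (-4.04), C8b (-3.79), C8a (-3.45) and C9 (-3.55) fell. Of 11 major urinary protein genes, 0 rose and 5 fell, and 0 and 6 adjusted over the list alone (median -0.75, adjusted p = 0.000734, and adjusted p = 0.574 with an estimated correlation), with Mup6 at -3.02, Mup5 at -1.59 and Mup20 at -1.32.

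The third comparison asked what differed in female livers labelled Bcl6-deficient. The largest increases were in Gpx3 (6.95 ± 0.14, adjusted p = 1.08e-07), Dnah11 (6.59 ± 0.21, adjusted p = 6.51e-07), the lens crystallin Crybb3 (5.74 ± 0.50), Marveld3 (5.50), the activin subunit Inhbb (5.34), Fgf11 (5.20), the imprinted gene Peg3 (4.97), Ankrd2 (4.97) and the kallikreins Klk1b4 and Klk1b22 (both 4.77). Cox8b became at least 145-fold higher, the adrenergic receptor Adra2c at least 143-fold, the organic cation transporter Slc22a2 at least 111-fold and the insulin receptor-related receptor Insrr at least 96.4-fold. The Cox8b bound was 89.3-fold without female Bcl6-deficient replicate 3 and 234-fold without replicate 4. The terminal complement components C9 (-4.71 ± 0.46) and C8b (-3.65 ± 0.40) and the female-biased Cyp2b13 (-4.39 ± 0.32) fell. The male-biased Elovl3 became at least 44.3-fold lower, while the male-biased Cyp7b1 did not pass (-0.26, adjusted p = 0.808).

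In all, 1939 genes changed in females, 1029 higher and 910 lower, 1072 of them at least 2-fold. Of the 1939, 1412 had a symbol. Other decreases were in Cyp4a14 (-3.93), the imprinted noncoding RNA Meg3 (-3.89), the bile acid transporter Slc10a2 (-3.69), Ildr2 (-3.60), the lysolipid transporter Mfsd2a (-3.54), Adrb3 (-3.35) and Raet1e (-3.32). Hsd3b5, Acsm2, Slc26a4 and the noncoding RNA Rian became at least 43.5-fold, 10.6-fold, 7.70-fold and 5.42-fold lower. The wild-type arrays differed for Hsd3b5 (3.64 and -1.29), whose bound was 7.87-fold without female wild-type replicate 3 and 240-fold without replicate 4, and for Acsm2, with 4.98-fold and 22.8-fold. The count was 1288 without female wild-type replicate 3, 883 without female Bcl6-deficient replicate 3 and 1022 without female Bcl6-deficient replicate 4. Without female wild-type replicate 3 the calls of Cyp4a14 (adjusted p = 0.126), Acsm2 (0.0514) and Rian (0.0689) ended. They also ended without female Bcl6-deficient replicate 4 (0.155, 0.075 and 0.0698), that of Rian also without female Bcl6-deficient replicate 3 (0.0512), and that of Hsd3b5 without either of these last 2 arrays (0.0925 without replicate 3 and 0.0623 without replicate 4).

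Of the 32 male-biased genes, 12 fell in females and 1 rose, and 18 and 2 adjusted over the list alone (median -0.66, camera adjusted p = 4.78e-07, and adjusted p = 0.598 with an estimated correlation). Of the 50 female-biased genes, 16 rose and 4 fell, and 22 and 9 adjusted over the list alone (median 0.49, adjusted p = 0.00895, and adjusted p = 0.598 with an estimated correlation). Cyp3a44 and the receptor Lifr rose by 3.20 and 2.84. Of the 35 growth hormone signalling genes, 8 rose and 4 fell, and 9 and 6 adjusted over the list alone. This list had a median of 0.28 (adjusted p = 0.0408, and adjusted p = 0.598 with an estimated correlation). Its call ended without female wild-type replicate 4 (adjusted p = 0.0945) or female Bcl6-deficient replicate 3 (adjusted p = 0.106). Socs2 rose by 2.74 ± 0.39, Prlr by 2.59 ± 0.15, Ghr by 2.57 ± 0.15 and Cux2 by 2.53 ± 0.23, while Igf1 (-0.17) and Stat5b (0.20) did not pass.

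Some sterol, lipid and interferon genes fell in females, though most members of these lists did not pass. Of 26 cholesterol synthesis genes, 10 fell and 0 rose, and 18 and 0 adjusted over the list alone (median -0.54, adjusted p = 2.03e-09, and adjusted p = 0.57 with an estimated correlation), among them Msmo1 (-1.19) and Cyp51 (-0.96). Of 32 lipogenesis genes, 11 fell and 3 rose, and 14 and 4 adjusted over the list alone (median -0.43, adjusted p = 0.00542, and adjusted p = 0.57 with an estimated correlation). The desaturase Scd1 fell by 2.93 and Pnpla3 rose by 3.12. Of 27 bile acid genes, 8 fell and 0 rose, and 10 and 1 adjusted over the list alone (median -0.26, adjusted p = 0.00267, and adjusted p = 0.57 with an estimated correlation), with Abcc3 at -3.16, Cyp39a1 at -1.81 and the nuclear receptor Nr0b2 at -0.90. Of the 40 interferon response genes, 12 fell and 0 rose, and 20 and 0 adjusted over the list alone (median -0.53, adjusted p = 1.87e-09, and adjusted p = 0.515 with an estimated correlation), among them Usp18 (-1.92), Ifit1 (-1.18) and Xaf1 (-1.02). Of 34 complement and coagulation genes, 5 fell and 3 rose, and 6 and 7 adjusted over the list alone (median -0.01, test upward, adjusted p = 0.912 by camera), with C8a at -2.72 and the coagulation factor F7 at 1.72.

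Some marker lists had an upward camera test in females with few or 0 members passing, and these calls were lost with an estimated correlation. Of 19 stellate cell genes, 0 rose and 0 fell, also over the list alone (median 0.28, adjusted p = 0.00895, and adjusted p = 0.598 with an estimated correlation). Of 25 fibrosis genes, 1 rose and 0 fell, also over the list alone (median 0.26, adjusted p = 0.0129, and adjusted p = 0.747 with an estimated correlation). Of 8 B and plasma cell genes, 0 rose and 0 fell, also over the list alone (median 0.58, adjusted p = 0.0305, and adjusted p = 0.691 with an estimated correlation). Of 20 endothelial genes, 2 rose and 0 fell, also over the list alone (median 0.06, mean 0.24, adjusted p = 0.0408, and adjusted p = 0.747 with an estimated correlation). Without female wild-type replicate 3 the calls of all 4 lists ended (adjusted p = 0.0606, 0.129, 0.411 and 0.0606 in this order). Without female Bcl6-deficient replicate 3 those of the B and plasma cell and endothelial lists ended (0.155 for both), and without female wild-type replicate 4 that of the endothelial list (0.122).

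**Figure D2:**
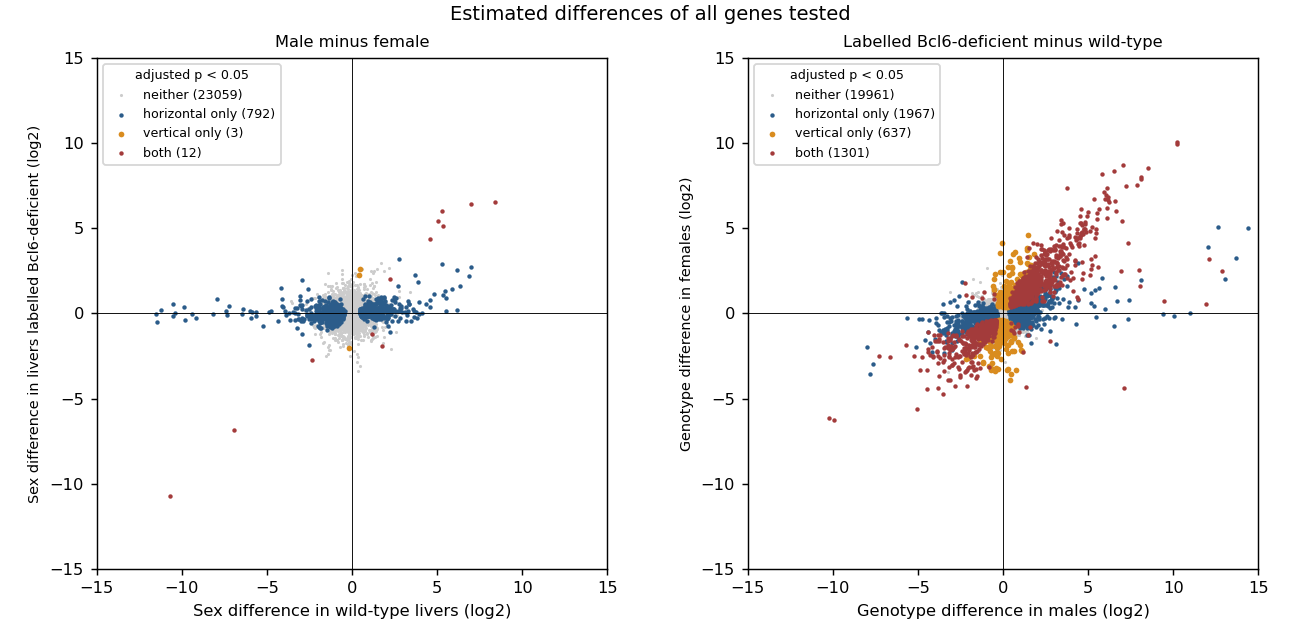
Estimated differences of the 23866 genes tested (log2), the sex difference on the left and the genotype difference on the right; each point is a gene, coloured by which of the differences passed an adjusted p of 0.05, and differences of genes under background in a group depend on the floor of the signal. Far fewer genes (15) passed for sex in livers labelled Bcl6-deficient than in wild-type livers (804), where the adjustment set a less strict cut. For genotype, 1301 genes passed in both sexes.

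Many genes changed the same way in both sexes. Dnah11 was 6.59 higher in each sex, Gpx3 6.06 and 6.95 higher in males and females, Ankrd2 5.47 and 4.97, Crybb3 4.94 and 5.74, Fgf11 4.64 and 5.20, and Inhbb 4.53 and 5.34. The kallikreins Klk1b22, Klk1b3, Klk1b4 and Klk1b24 were 4.85, 4.68, 4.63 and 4.57 higher in males and 4.77, 4.69, 4.77 and 4.73 higher in females, and as nearly identical genes they may share probe signal. The vasopressin receptor Avpr1a (-2.89 and -2.93), the adenosine receptor Adora1 (-3.00 and -3.02), the retinoic acid hydroxylase Cyp26b1 (-3.19 and -3.12), Enpp3 (-2.97 and -2.68) and the transporter Slco1a1 (-3.81 and -2.89) were lower in both sexes. In total 771 genes were higher in both sexes, against 74 if the calls of the sexes were independent, and 509 were lower in both, against 59.2. Only 21 genes changed in opposite directions, against 132.4. Cyp2b13 was among them, at least 61.1-fold higher in males and at -4.39 in females. Both comparisons used 1 shared estimate of each gene's spread, so their calls are coupled and the counts under independence are only a rough reference. The shared spread does not set the direction of a change, which was the same for 1280 genes and opposite for 21. Across genes, which are not independent replicates, the changes of the sexes correlated at r = 0.666 (rho = 0.484), and they share no array. The 1280 genes changed alike became 686 without female Bcl6-deficient replicate 3 and 797 without female Bcl6-deficient replicate 4. The Slco1a1 call in females ended without female wild-type replicate 3 (adjusted p = 0.092), female Bcl6-deficient replicate 4 (0.203), either male wild-type array (0.061), male Bcl6-deficient replicate 3 (0.0533) or male Bcl6-deficient replicate 4 (0.0534).

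The fourth comparison asked what sex difference was left in livers labelled Bcl6-deficient. Several genes that parted the sexes in wild-type liver had close levels in males and females here. Cyp2b9 was at 6.87 ± 0.16 in males and 6.95 ± 0.04 in females (SD, n = 2), Cux2 at 2.08 ± 0.03 and 2.23 ± 0.34, Cyp7b1 at 4.18 ± 0.46 and 4.10 ± 0.08, Cyp2d9 at 3.16 ± 0.27 and 3.23 ± 0.10 and Socs2 at 3.76 ± 0.76 and 3.34 ± 0.64. Cyp4a12a (2.20, adjusted p = 0.915) and Hsd3b5 (at least 3.24-fold, adjusted p = 1.0) had higher means in males without passing. Of the 50 female-biased genes, 0 passed in either direction in limma, and 1 higher in males adjusted over the list alone (median -0.03, mean 0.02, camera adjusted p = 0.823). Of the 32 male-biased genes, 1 passed, lower in males, and 4 higher and 1 lower adjusted over the list alone (median 0.37, or 0.29 with bounds, adjusted p = 4.29e-06, and adjusted p = 0.57 with an estimated correlation). Of the 40 interferon response genes, 0 passed, also over the list alone (median 0.30, higher in males, camera adjusted p = 2.58e-12, and adjusted p = 0.254 with an estimated correlation). Camera also called other lists, among them T and natural killer cell (0.52, adjusted p = 3.69e-05), cell cycle (0.47, 3.98e-05) and pericentral genes (-0.34, 1.73e-05). These calls too were lost with an estimated correlation.

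In all, 15 genes differed between the sexes in livers labelled Bcl6-deficient, 9 higher in males and 6 higher in females, and 1132 had an unadjusted p under 0.05. Xist (at least 25.1-fold) and a second probe named XIST (at least 448-fold) were higher in females. Ddx3y, Kdm5d and Uty were at least 10.2-fold, 13.5-fold and 8.57-fold higher in males, and Eif2s3y was 6.56 higher. Of 3 further features without a gene symbol, 2 were higher in males and 1 in females. Eif2s3x, the X-linked counterpart of Eif2s3y, was 2.03 higher in males, as in wild-type livers (2.22), and its probe may share signal with Eif2s3y. The bile acid transporter Slc10a2 was 2.63 higher in males, and Fndc5 (-2.04), Susd4 (-1.89) and the growth factor Bmp7 (-1.21) higher in females. Of the 804 genes that differed between wild-type sexes, 10 differed in the same direction here. Of these, 6 were on the list of sex chromosome genes, and the other 4 were the second XIST probe and the 3 features without a gene symbol. Because p-values were adjusted within each comparison, the cut was stricter here. In limma, Nr0b2 passed in wild-type livers (0.67, adjusted p = 0.0214) but not here with a larger difference (0.84, adjusted p = 0.092). The fall in counts is therefore not a measure of how far the differences themselves fell. Susd4 and Bmp7 differed in the opposite direction in wild-type livers (1.78 and 1.19). The count was 8 without either male wild-type array. Without male Bcl6-deficient replicate 4 the calls of Kdm5d (adjusted p = 0.0561), Uty (0.103), Eif2s3y (0.173), Fndc5 (0.0744) and Bmp7 (0.27) ended. Without male Bcl6-deficient replicate 3 those of Uty (0.0941), Eif2s3y (0.0947) and Bmp7 (0.0755) ended, and without female Bcl6-deficient replicate 3 those of Slc10a2 (0.0831), Fndc5 (0.157) and Bmp7 (0.334). Without female Bcl6-deficient replicate 4 those of Slc10a2 (0.148), Fndc5 (0.203) and Bmp7 (0.0958) ended. Without male wild-type replicate 3 those of Slc10a2, Uty and Fndc5 (each 0.0758), Eif2s3y (0.0905) and Bmp7 (0.126) ended. Without male wild-type replicate 4 those of Slc10a2 (0.0808), Uty (0.0806), Fndc5 (0.0805), Eif2s3y (0.0902) and Bmp7 (0.126) ended. That of Bmp7 also ended without female wild-type replicate 3 (0.0572) or replicate 4 (0.0552).

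A second measure selected sex-different genes on the wild-type arrays of one replicate number, with a difference of at least 1, and measured them on the arrays of the other number. Of the male-higher genes (750 and 676 in the 2 directions of the split), 5.58% and 15.6% of the wild-type difference was left in livers labelled Bcl6-deficient, 10.6% on average. Of the female-higher genes (898 and 973), -13.1% and 6.28% was left, -3.40% on average, where a negative share is a reversed difference. Over the alternatives the averages ranged from 6.97% to 13.8% for male-higher genes and from -7.19% to 2.18% for female-higher genes. In single directions of the split they ranged from -2.24% (selection at 0.58) to 18.3% and from -27.2% to 12.8%. Both signs occurred for either set, so the sign and exact size of the share left were not settled. In no setting was more than 18.3% left. Each share is a ratio of medians: -13.1% was -0.096 in livers labelled Bcl6-deficient against 0.734 in wild-type livers.

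**Figure D3:**
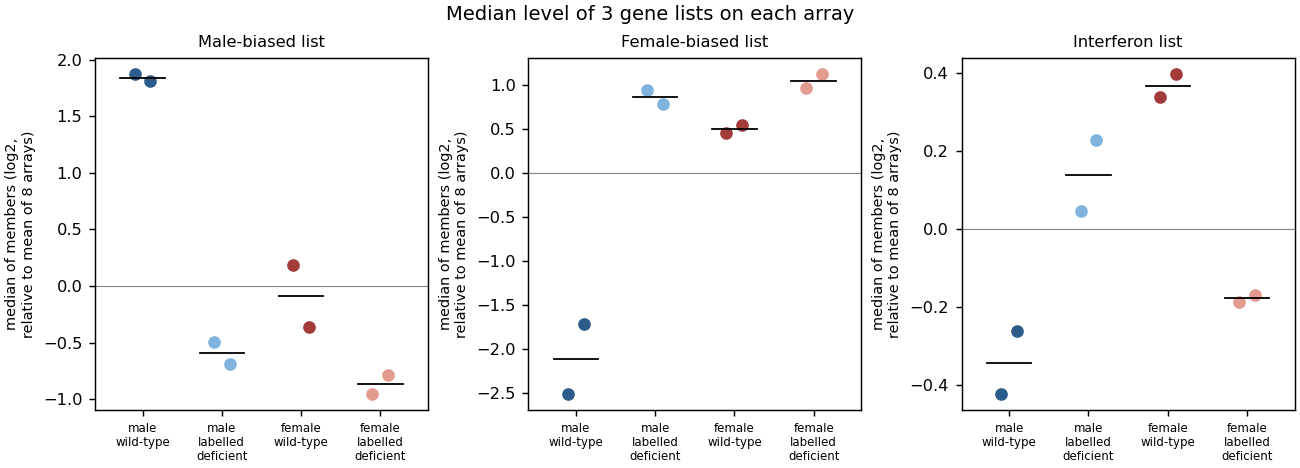
Median level of the genes of 3 fixed lists on each of the 8 arrays (log2, relative to the mean of the 8 arrays); each point is an array and each line a group mean. The female-biased list is at -2.51 and -1.72 in male wild-type livers and between 0.45 and 1.12 on the other 6 arrays, and the interferon list moves up in males and down in females with the genotype label.

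The fifth comparison asked whether the genotype difference itself depended on sex, as the male difference minus the female difference. Female-biased genes had the largest dependence. The male difference exceeded the female one by 7.26 ± 0.54 for Cyp2b9 (adjusted p = 0.00056), 5.68 ± 0.51 for Cyp2b10, 4.99 ± 0.60 for Acot3, 4.0 ± 0.45 for Mfsd2a and 2.55 ± 0.21 for Prlr. Mfsd2a was at -3.54 in females and 0.46 in males (adjusted p = 0.378), so its value came mostly from a decrease in females. Nat8 (-3.83 ± 0.44), Susd4 (-3.68 ± 0.21), Cyp2d9 (-3.29 ± 0.19), the glutathione transferase Gstp1 (-2.84 ± 0.19) and the transcription factor Onecut1 (-2.40 ± 0.26) went the other way. In all, 176 genes passed, 128 positive and 48 negative, and 142 of the 176 had a symbol. Of the 50 female-biased genes, 28 were positive and 0 negative, and 43 and 0 adjusted over the list alone (median 2.51, camera adjusted p = 1.93e-51, and adjusted p = 0.0378 with an estimated correlation). Of the 32 male-biased genes, 9 were negative and 0 positive, and 18 and 0 adjusted over the list alone (median -1.31, adjusted p = 4.59e-18, and adjusted p = 0.322 with an estimated correlation). Of the 40 interferon response genes, 8 were positive and 0 negative, and 30 and 0 adjusted over the list alone (median 0.92, adjusted p = 6.83e-28, and adjusted p = 0.0378 with an estimated correlation). They included Gbp3 (2.43 ± 0.24) and Ifit1 (1.83 ± 0.22). These interaction calls of the female-biased and interferon lists were the only list calls among the 5 comparisons that held with an estimated correlation. The interaction of the growth hormone receptor Ghr (-0.31, adjusted p = 0.653), of Socs2 (-2.44, adjusted p = 0.11) and of Cish (-3.83, adjusted p = 0.0841) did not pass. The count was 99 without male wild-type replicate 3, 105 without male Bcl6-deficient replicate 4, 81 without female Bcl6-deficient replicate 3 and 76 without female Bcl6-deficient replicate 4.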

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

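The tests of explanations in this part were chosen after the results were seen, except the spike-in test, while the interaction tests of genes and lists were planned. The results below are here because the genotype difference itself differed between males and females in limma's interaction test, given as the male difference minus the female difference on the log2 scale. This held for 176 genes and, by camera at its preset correlation, for 19 of the 36 gene lists, of which 2 (female-biased and interferon) held with an estimated correlation.

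Female-biased genes were again foremost. Cyp2b9 (7.26), Cyp2b10 (5.68), Acot3 (4.99), Cux2 (5.49), Mfsd2a (4.0), Mt1 (3.58), Acnat2 (3.42), Cyp17a1 (3.34), the aldose reductase Akr1b7 (2.89), Prlr (2.55) and the transporter Slco1a4 (2.41) had a higher genotype difference in males. Nat8 (-3.83), Susd4 (-3.68), Cyp2d9 (-3.29), Gstp1 (-2.84), Onecut1 (-2.40), Bmp7 (-2.40), Ttc39c (-2.11), Elovl3 (-4.10) and Cyp2d34 (-4.07) had a lower one. Cyp2b13 (11.49), Sult2a2 (11.05) and Sult2a6 (10.43) were not above background in male wild-type livers, nor was Cux2. Elovl3 was not above background in female livers labelled Bcl6-deficient, nor was Nat8f5, and Nat8f5 and Cyp2d34 were above it on 1 array only in male livers labelled Bcl6-deficient. The fitted values of these 7 genes depend on the floor of the signal and are no bounds. The interferon genes Gbp3 (2.43), Ifit1 (1.83), Igtp (1.82) and Gbp6 (1.68) and the sulfotransferase Sult1a1 (1.56) were higher. Further genes were Vldlr (3.78), Slc16a5 (3.41), C6 (-2.78), Alas2 (-2.15), Adh6-ps1 (-2.13), Nat8f5 (-4.75), the oestrogen receptor Esr1 (1.65), the Bcl6 corepressor Bcor (1.27), Pdk4 (1.68), Elovl5 (1.27), Cyp2d11 (-1.12), Zfp36 (1.23), Nqo1 (1.79), Ly6c2 (2.21) and Hbb-b2 (1.01). Calls that ended without male wild-type replicate 3, with their adjusted p, were Vldlr (0.0857), Slc16a5 (0.146), C6 (0.134), Alas2 (0.0779), Adh6-ps1 (0.157), Nat8f5 (0.0524), Sult2a2 (0.067), Sult2a6 (0.0853), Bcor (0.0575), Pdk4 (0.143), Elovl5 (0.136), Cyp2d11 (0.0723), Igtp (0.103), Gbp6 (0.0524), Zfp36 (0.0788), Nqo1 (0.0606), Ly6c2 (0.143) and Hbb-b2 (0.142). Slc16a5 (0.0797), C6 (0.0828), Alas2 (0.0684), Adh6-ps1 (0.131), Sult2a2 (0.0624), Sult2a6 (0.0718), Pdk4 (0.102), Elovl5 (0.0684), Igtp (0.079), Zfp36 (0.0685), Ly6c2 (0.0596) and Hbb-b2 (0.0684) ended without male wild-type replicate 4. Vldlr (0.0606), Slc16a5 (0.0638), C6 (0.0834), Adh6-ps1 (0.0797), Sult2a2 (0.0503), Sult2a6 (0.0563), Bcor (0.0545), Pdk4 (0.0965), Zfp36 (0.0585), Nqo1 (0.0563), Ly6c2 (0.0721) and Hbb-b2 (0.067) ended without male Bcl6-deficient replicate 3. Vldlr (0.111), Slc16a5 (0.15), C6 (0.0786), Adh6-ps1 (0.17), Sult2a2 (0.059), Sult2a6 (0.0766), Esr1 (0.0587), Bcor (0.0674), Pdk4 (0.106), Elovl5 (0.129), Cyp2d11 (0.0688), Igtp (0.0875), Zfp36 (0.07), Nqo1 (0.0642) and Hbb-b2 (0.151) ended without male Bcl6-deficient replicate 4. Ly6c2 (0.0788) and Hbb-b2 (0.0856) ended without female wild-type replicate 3. Adh6-ps1 (0.0628), Pdk4 (0.0939), Elovl5 (0.0721) and Hbb-b2 (0.0626) ended without female wild-type replicate 4. Vldlr (0.107), Slc16a5 (0.141), C6 (0.12), Alas2 (0.0784), Adh6-ps1 (0.154), Sult2a2 (0.0645), Sult2a6 (0.0744), Esr1 (0.0545), Bcor (0.088), Elovl5 (0.13), Cyp2d11 (0.0885), Igtp (0.102), Zfp36 (0.0972), Nqo1 (0.0874), Ly6c2 (0.15) and Hbb-b2 (0.107) ended without female Bcl6-deficient replicate 3. Vldlr (0.071), Slc16a5 (0.106), C6 (0.0909), Alas2 (0.0731), Adh6-ps1 (0.0731), Sult2a6 (0.0779), Esr1 (0.0789), Bcor (0.0854), Pdk4 (0.0864), Elovl5 (0.152), Cyp2d11 (0.118), Igtp (0.0878), Gbp6 (0.0643), Zfp36 (0.0709), Nqo1 (0.071), Ly6c2 (0.107) and Hbb-b2 (0.188) ended without female Bcl6-deficient replicate 4.

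The lists that differed by their camera test had interaction medians of 2.51 (female-biased), -1.31 (male-biased), 0.92 (interferon), 1.19 (cell cycle), 1.16 (T and natural killer cell), 0.96 (neutrophil), 0.76 (erythroid), 0.66 (Kupffer cell and macrophage), -0.51 (endoplasmic reticulum stress), 0.48 (lymphoid Bcl6 targets), 0.45 (cholesterol synthesis), 0.44 (lipogenesis), 0.44 (B and plasma cell), 0.27 (drug metabolism), 0.18 (fibrosis), 0.17 (endothelial), 0.13 (stellate cell), 0.0504 (PPARA and fatty acid oxidation) and 0.0461 (acute phase). With an estimated correlation the calls other than the female-biased and interferon lists (adjusted p = 0.0378 for both) were lost, with an adjusted p from 0.219 (lipogenesis) to 0.705 (PPARA). Calls that ended without male wild-type replicate 3, with their adjusted p, were PPARA (0.102), fibrosis (0.143), endothelial (0.484), stellate (0.0526), B cell (0.143) and erythroid (0.0526). Stellate (0.126) and B cell (0.0589) ended without male wild-type replicate 4. Endothelial (0.0524) and B cell (0.15) ended without male Bcl6-deficient replicate 3. Fibrosis (0.561), endothelial (0.0692), stellate (0.46), B cell (0.0517) and erythroid (0.0747) ended without male Bcl6-deficient replicate 4. Endothelial (0.0818) and erythroid (0.0609) ended without female wild-type replicate 3. Lymphoid Bcl6 targets (0.0522), fibrosis (0.122), stellate (0.202) and B cell (0.956) ended without female wild-type replicate 4. Endothelial (0.174), stellate (0.174) and B cell (0.175) ended without female Bcl6-deficient replicate 4.

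The first pattern weighed was the expression that differed between arrays labelled Bcl6-deficient and wild-type, because genotype and slide column coincide. A column effect is the same for both sexes, so it argues against this that the female-biased list had an interaction median of 2.51 (2.42 to 2.77 with any 1 array left out). For genes changed alike in both sexes a column effect cannot be told apart from one of the genotype, because no column held both genotypes. All 7 spike-in transcripts above background on all arrays were higher in the inner columns, by 0.04 to 0.10 in males and 0.23 to 0.29 in females. Over all genes the median difference was -0.05 in males and -0.02 in females. The stellate (0.28), fibrosis (0.26) and bile acid (-0.26) list medians in females were of similar size to the spike-in differences. Spike-ins show an array-wide effect and not one of single probes. A comparison with the size of the changes of the genes changed alike decides nothing, since these genes were chosen by passing the test. Exchanged sex labels were excluded by the brightest probes of Xist and 3 Y-linked transcripts (Ddx3y, Uty and Kdm5d), which matched the label on 8 of 8 arrays. Eif2s3y was left out of this check, and 1 of its probes was above background on 1 female array. A genotype effect stays open as the biological explanation.

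The second pattern was the Bcl6 signal, which was not lower in arrays labelled Bcl6-deficient. Exchanged genotype labels would leave the female-biased list sex-different in the arrays labelled Bcl6-deficient, as intact livers differ. Its median there was -0.0297 (from -0.12 without male Bcl6-deficient replicate 3 to 0.17 without replicate 4, so its sign rests on single arrays), against -2.82 (-2.95 to -2.45 with any 1 array left out) in those labelled wild-type, which argues against an exchange. A probe outside the deleted part of the gene stays open: the array has 1 Bcl6 probe and the deleted part is not known here, so this cannot be told apart from a deletion that did not lower the transcript.

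The third pattern was the interferon list, higher in males (median 0.50) and lower in females (-0.53) labelled Bcl6-deficient. The wild-type sexes already differed (median -0.66, male minus female). List medians per array were -0.43 and -0.26 in male and 0.34 and 0.40 in female wild-type livers. In livers labelled Bcl6-deficient they lay between these, at 0.05 and 0.23 in males and -0.19 and -0.17 in females. The opposite directions therefore also describe a wild-type sex difference that was not kept. The slide column would move both sexes alike, which the interaction median of 0.92 (0.81 to 1.06 with any 1 array left out) argues against. A hepatocyte share that differed with the genotype stays open. A lower share would raise the lists of other cell types, so alone it could bear on the rise in males and not on the fall in females. The hepatocyte list itself did not pass camera in males (median -0.09, adjusted p = 0.49) or in females (0.06, adjusted p = 0.639). In females the stellate list had an upward camera test (median 0.28, adjusted p = 0.00895), with 0 of 19 genes past the threshold over all genes or over the list alone. So had the fibrosis (0.0129), B and plasma cell (0.0305) and endothelial (0.0408) lists, but with an estimated correlation these calls were lost (adjusted p = 0.598 for stellate, 0.691 for B and plasma cell and 0.747 for the others). They ended without female wild-type replicate 3 (adjusted p = 0.0606 for stellate and endothelial, 0.129 for fibrosis and 0.411 for B and plasma cell), and those of the B and plasma cell and endothelial lists without female Bcl6-deficient replicate 3 (0.155 for both) and of the endothelial list without female wild-type replicate 4 (0.122). Macrophage content stays open as well, the Kupffer cell and macrophage list having a median of -0.32 in females without passing (adjusted p = 0.121), and an effect of the genotype on interferon genes that depends on sex may be the biological explanation and was not tested apart from these.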

How the results depend on the processing

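No alternative was chosen after the results were seen. Of the named genes (563 results), none changed direction where the main value or the alternative passed the threshold. A change of sign with neither past it was counted as kept, here and for the lists. Of 4945 values under other settings 4661 kept their side of the threshold, 269 became weaker and 15 stronger. Of 4504 with an array left out 3914 kept it, 552 became weaker and 38 stronger. Of the lists other than the sex-biased ones (170 results), 985 of 1190 values under other settings kept their side, 170 became weaker, 31 stronger and 4 reversed, and with an array left out 1212 of 1360 kept it, 79 became weaker, 54 stronger and 15 reversed. Over the scalings and contrasts the median of all genes was at most 0.0794 (wild-type sex, normexp).

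Counts moved by over 1.5 times under these settings. Without a filter, where more genes are tested, the counts were 433 (wild-type sex), 2178 (males), 8 (sex in livers labelled Bcl6-deficient) and 75 (interaction). Without the intensity trend they were 474, 9 (sex, labelled Bcl6-deficient) and 93 (interaction). With only the 4 arrays compared, which leaves fewer samples, they were 531 and 9 for the sex comparisons. With genes above background on all 8 arrays, which removes the sex-specific transcripts, 5 were left in livers labelled Bcl6-deficient. With an array left out, its partner was assumed to vary like the other groups, and counts ranged from 364 to 737 (wild-type sex), 1740 to 3484 (males), 883 to 1805 (females), 8 to 19 (sex, labelled Bcl6-deficient), 76 to 194 (interaction) and 686 to 1169 (changed alike in both sexes).

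The male-biased list lost its camera call with an estimated correlation in all 5 contrasts (medians 1.77, -2.64, -0.66, 0.37 and -1.31), and with fry in females (-0.66, adjusted p = 0.0709) and between sexes labelled Bcl6-deficient (0.37, adjusted p = 0.778). The female-biased list lost it with an estimated correlation in wild-type sex (-2.82), males (2.74) and females (0.49), and with fry in females (0.49, adjusted p = 0.122). In wild-type sex, males and the interaction both lists passed fry. Its adjusted p was 0.000269, 0.000171 and 0.000923 for the female-biased list and 0.00699, 0.00375 and 0.0496 for the male-biased list. For the interferon list fry gave 0.00656, 0.0129, 0.0422, 0.102 and 0.00452 in the order of the report. The median is the same by construction, since only the set test changed. Bcl6 ranged from 0.93 to 1.48 in males and 0.26 to 2.41 in females with an array left out, and passed without either female wild-type array in males (1.21) and without female wild-type replicate 4 in females (2.41).

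Reversed medians were at most 0.15 from 0, and 6 of them passed camera. PPARA: 0.0462 and 0.0679 (wild-type sex, without male or female wild-type replicate 3; range -0.11 to 0.0679), 0.0328 (males, without male Bcl6-deficient replicate 4, adjusted p = 0.0441; from -0.20), -0.11 (sex, labelled Bcl6-deficient, without male Bcl6-deficient replicate 3, adjusted p = 0.00281; to 0.20), and -0.11, -0.05 and -5e-04 (interaction; to 0.24). Acute phase, wild-type sex: -0.056 (normexp, adjusted p = 0.0035), -0.10 (quantile, 0.028), -0.12 and -0.15 (without male wild-type replicate 3, 0.0296, or female wild-type replicate 4, 0.00987; to 0.26). Acute phase, interaction: -0.06, -0.03, -0.12 and -0.02 (to 0.38). Others: hepatocyte -0.0442 (wild-type sex, quantile), B cell 0.0254 (wild-type sex, normexp), periportal -0.13 (to 0.52) and Kupffer cell -0.0071 (to 0.44) (sex, labelled Bcl6-deficient, without male Bcl6-deficient replicate 4). Where no construction is named, the cause was not tested.

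With the replicate number as a replicate block, counts were 1036, 3800, 2210, 14 and 255 in the order of the report, of which 786, 3223, 1900, 12 and 172 were called without it, and 1480 genes changed alike. The labels do not say that the numbers pair samples. Replicate differences correlated at 0.006 to 0.321 between groups across genes, which are not independent replicates. The number is also the slide row, and a row effect is not excluded. Signal over background limits what can be seen of genes under the lowest level above background (-4.38 to -3.85), whose changes are bounds.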

Other observations

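The count over splits in this part was chosen after the results were seen, while the gene and list tests were planned. Cell type, clock and stress genes gave further values for livers labelled Bcl6-deficient. The proliferation marker Mki67 rose by 2.21 in males and 1.32 in females, and the clock-controlled gene Noct by 4.68 and 2.40. The endothelial von Willebrand factor Vwf rose by 2.20 and 2.17, and the pericentral glutamate transporter Slc1a2 by 1.91 and 2.03. Of the 19 clock genes, 4 rose and 1 fell in males, and 5 and 2 adjusted over the list alone (median 0.19, or 0 with bounds, camera adjusted p = 0.49). In females 1 of them rose and 1 fell, and 3 and 1 adjusted over the list alone (median -0.0467, adjusted p = 0.77). Of the 12 pericentral genes, 1 rose and 2 fell in each sex, and 2 and 3 in males and 1 and 3 in females adjusted over the list alone. Those that fell were Lgr5, at -1.35 in males and -1.20 in females, Glul at -0.78 in males and Rnase4 at -0.66 in females. The list had medians of -0.22 and -0.13 (camera adjusted p = 0.642 and 0.639). Calls ended for Lgr5 in males without male wild-type replicate 3 (adjusted p = 0.0594) or male Bcl6-deficient replicate 4 (0.0659) and in females without female wild-type replicate 4 (0.0966) or female Bcl6-deficient replicate 3 (0.155). That of Glul ended without male wild-type replicate 3 (0.0836), male wild-type replicate 4 (0.153) or male Bcl6-deficient replicate 4 (0.149), and that of Rnase4 without female Bcl6-deficient replicate 3 (0.0937). The periportal dehydrogenase Hsd17b13 was at -1.17 in males and -1.59 in females. Of 11 periportal genes, 2 fell and 0 rose in males, also over the list alone (median -0.0131, adjusted p = 0.365), and 2 fell and 0 rose in females, and 3 and 0 adjusted over the list alone (median -0.33, adjusted p = 0.0247, and adjusted p = 0.747 with an estimated correlation). This call in females ended without female wild-type replicate 3 (adjusted p = 0.0795) or female Bcl6-deficient replicate 4 (0.0939). Of 16 oxidative stress genes, 3 rose and 3 fell in males, and 5 and 3 adjusted over the list alone (median 0.05, camera adjusted p = 0.635), with Gpx2 (2.26), Nqo1 (1.90) and Hmox1 (1.25) higher and Aox1 (-1.15) among those lower. In males the sinusoidal marker Lyve1 (1.12), the stellate marker Colec11 (0.74) and the neutrophil marker S100a9 (1.02) rose. Of 25 fibrosis genes, 5 rose in males and 0 fell, and 10 and 0 adjusted over the list alone (median 0.51, camera adjusted p = 9.12e-06, and adjusted p = 0.515 with an estimated correlation). Of 27 cell cycle genes, 4 rose in males and 0 fell, and 4 and 0 adjusted over the list alone (median 0.80, or 0.75 with bounds, adjusted p = 1.81e-05, and adjusted p = 0.515 with an estimated correlation). In females 1 of them, Mki67, rose and 0 fell, also adjusted over the list alone (median -0.30, adjusted p = 0.478).

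Some genes were above background on all 4 arrays of one genotype label and on none of the other. The adrenergic receptor Adra2c was at least 97.3-fold higher in males and 143-fold in females labelled Bcl6-deficient, Slc22a2 at least 33.7-fold (21.9-fold without male Bcl6-deficient replicate 3 and 51.9-fold without replicate 4) and 111-fold, the ceramidase Acer1 at least 23.8-fold and 36.4-fold, and the collagen Col22a1 at least 22.8-fold and 73.1-fold. Olig1 went the other way, at least 13.2-fold and 3.86-fold lower. In total 128 genes were above background on all 4 arrays labelled Bcl6-deficient and no wild-type array, 88 of them past the threshold in both sexes, and 42 the other way, 17 of them past it. Of the 35 splits of the 8 arrays into 4 and 4, 1 split, the real one, gave as many as 128 on a side. The highest other count was 31. The genes had been kept by a filter on the real groups, which holds down the counts of other splits. The real split is also that of the slide columns, so the count neither excludes chance nor tells genotype from column.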
